A study of Medicago truncatula with 2 samples.

How the data were processed

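Small RNA of young leaves was sequenced in 2 libraries of 1 group. Per the labels' protocols, total RNA was extracted with Trizol and low molecular weight RNA was isolated. A pre-adenylated 3′ adapter was joined with truncated T4 RNA ligase 2, unused adapter was removed enzymatically, and a 5′ adapter was joined with T4 RNA ligase 1. The product was reverse transcribed and amplified by PCR, and a band near 147 bp was cut from a polyacrylamide gel. Plants were grown at 23 °C for 18 h and 16 °C for 6 h per day, per the labels' protocols.

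The deposited file is a table of the whole series with raw read counts, as the values show: each row is a distinct sequence, followed by whole-number counts in each library that are not normalized. The software that trimmed the adapters and collapsed the reads, and any genome build, are not given in the sources used here. Tests on the file showed sequences of 18 to 32 nt made of A, C, G and T only, no sequence listed more than once, and none with 0 reads in both libraries. The 9156107 rows therefore show a length limit, and they include reads identical to miRNAs of other organisms, so a filter to the genome was not detectable. Of the 5 most abundant reads, 3 match a listed miRNA sequence from end to end, with no adapter bases left on them. Without those bases, reads cannot be collapsed into molecules, so counts are reads and can include PCR copies. Each library column was matched to its sample by title, and 0 columns were left unmatched. No genome sequence was used here, so reads were not mapped, no coordinates are given, and the planned classes of genome annotation were not analysed here.

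Levels are RPM of all reads of a library. Sequences are printed as DNA letters. Length and 5′ base shares were computed over reads of 18 to 26 nt or within a length, with 95% Wilson intervals that cover counting error only. A read of 18 to 26 nt was assigned to a family when nt 2 to 17 of a listed mature sequence matched without mismatch, starting at read position 1 to 4. The lists of 40 Medicago families and the lists of miRNAs of other plants and of animals were written from general knowledge before the data were examined, as were the design, the rule for named families and the alternatives. Some listed sequences turned out to differ from the reads by 1 or 2 bases. They were left as written, and the result with up to 2 mismatches is given beside them. That match also required a read to start at the listed 5′ end and to be at least as long as the listed sequence. miRNAs of near-identical sequence within a family cannot be told apart by this match.

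The rule for named items took families with at least 10 RPM in both libraries, at most the 25 with the highest mean, the 5 most abundant sequences of 18 to 26 nt, and any family at least 2-fold apart with at least 100 reads in 1 library. Families were compared between the libraries by chi-square tests of counts, or Fisher's exact test under 10 reads, with Benjamini-Hochberg adjustment. Intervals of ratios are exact binomial. With 1 group and no contrast, no differential test across groups was made. edgeR 4.0.16 (TMM) and DESeq2 1.42.0 (size factors) served only as alternative scalings, in R 4.3.3. Other steps used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

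The code was tested on simulated data. Of 673 planted miRNA reads 100% were assigned to their family, and of 20000 random reads 0 were assigned. The planted reads were listed sequences with changed ends and no substitutions, so this checks the code and not the recovery of real variants. In simulated counts of the 30 families with enough reads, the per-family test called 0.0667% of families with no change and 100% of those with a planted 1.5-fold or 2-fold change. These counts held counting noise only, so the rate of false calls does not carry over to libraries that vary more. The search for antisense partners recovered the planted overlap of 22 nt and no other. Depth was near equal, at 11509999 and 11390459 reads. Alternatives were a minimum of 2 reads per sequence, sequences found in both libraries, distinct sequences in place of reads, other denominators, other match rules, other pseudocounts, other scalings, and leaving out each library.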

Results

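Small RNA was sequenced from young leaves of Medicago truncatula, a model legume, taken from flowering plants aged 2 months that received no special treatment. Both libraries were made from 1 µg of total RNA with High-Definition adapters, which carry degenerate bases at the ends that are ligated, so that an RNA can meet an adapter end that ligates well to it. The 2 libraries belong to 1 group, and the series holds no library made with another adapter. The design therefore implies a description of the leaf small RNA population and a comparison of the libraries with each other. The labels do not say whether the libraries came from separate plants, so the spread between them may be technical.

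Library 1 held 11509999 reads and library 2 held 11390459 reads of 18 to 32 nt. They contained 4876487 and 5364377 distinct sequences. A count of 0 allows a level of up to 0.261 RPM, reads scaled to a common library total, in library 1 and 0.263 RPM in library 2. Of the 9156107 distinct sequences in both libraries together, 1084757 (11.8%) were found in both, and these carried 57.2% of the reads of library 1 and 55.0% of the reads of library 2. Sequences with a single read made up 71.9% of the distinct sequences of library 1 and 78.0% of those of library 2. Intervals and floors cover counting error only, and with 2 libraries an exact paired permutation test cannot give a two-sided p below 0.5, so values are given with their spread, and the tests of read counts given for families compare these libraries only.

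The leaf population was dominated by 24-nt RNA, the size class made mainly for RNA-directed DNA methylation of repeats in plants. Among reads of 18 to 26 nt, 24-nt RNA took 49.1% ± 0.791 (SD, n = 2) and 21-nt RNA, the class that holds most miRNAs, took 21.5% ± 0.846 (SD, n = 2). The 23-nt class followed with 9.05% ± 0.0468 and the 22-nt class with 7.68% ± 0.0884 (SD, n = 2). The 24-nt share was 48.5% in library 1 (95% Wilson interval 48.5 to 48.6) and 49.7% in library 2 (49.6 to 49.7). It exceeded the 21-nt share by 26.4 percentage points in library 1 and 28.7 points in library 2, and neither class differed by more than 1.20 points between the libraries. Among distinct sequences the gap was wider, with 66.2% ± 0.805 at 24 nt and 6.32% ± 0.20 at 21 nt (SD, n = 2). Over the reads of sequences seen in both libraries, the 24-nt share exceeded the 21-nt share by 2.44 points.

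**Figure D1:**
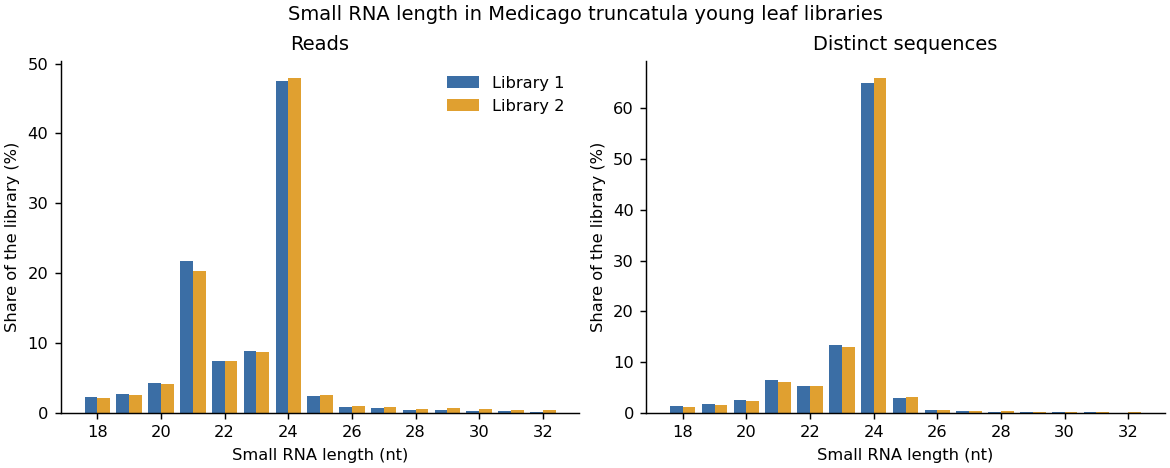
Share of reads (left) and of distinct sequences (right) at each length from 18 to 32 nt, in percent of all reads or distinct sequences of library 1 (blue) and library 2 (orange). Both libraries peak at 24 nt, and the peak at 21 nt is much lower among distinct sequences than among reads.

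The 21-nt and 24-nt classes differed in reads per sequence but little in the share of distinct sequences found again. A distinct 21-nt sequence was read 7.50 ± 0.677 times on average and a distinct 24-nt sequence 1.63 ± 0.129 times (SD, n = 2). Of the distinct 24-nt sequences of library 1, 25.9% were also found in library 2, and 69.8% had a single read; for 21-nt sequences these shares were 22.9% and 70.3%. Of the reads of 21 nt, 87.7% in library 1 and 86.8% in library 2 belonged to sequences found in both libraries, compared with 42.9% and 39.2% of the 24-nt reads.

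The 5′ base, which in plants is known to guide the loading of small RNA into different ARGONAUTE proteins, followed the size class. U began 72.5% ± 1.00 of 21-nt reads and 57.6% ± 0.802 of 22-nt reads, and A began 45.6% ± 0.301 of 24-nt reads (SD, n = 2). Only 10.6% ± 0.114 of 21-nt reads began with A (SD, n = 2). Each of these shares differed by under 2 points between the libraries, far less than the differences between size classes. Counted over distinct sequences, the 5′ U share of 21-nt RNA was 41.1% ± 0.923 and the 5′ A share of 24-nt RNA 44.0% ± 0.389 (SD, n = 2). With the reads assigned to the listed families removed, U began 56.5% ± 2.08 of 21-nt reads (SD, n = 2). The remainder is not free of miRNA reads. It kept a 21-nt read at 11435 RPM that begins with U and differs from a listed miR156 sequence by 1 base.

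**Figure D2:**
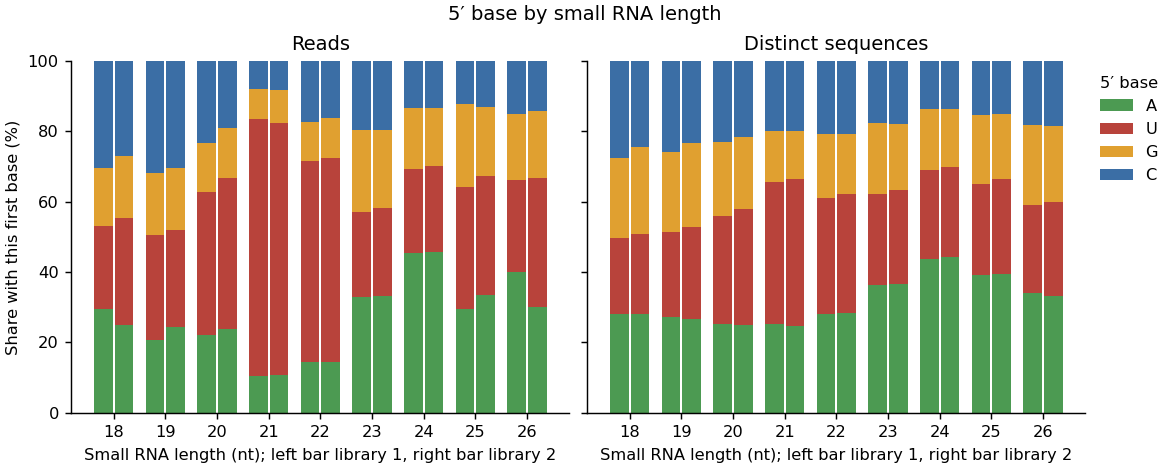
Share of reads (left) and of distinct sequences (right) that begin with A, U, G or C at each length from 18 to 26 nt, in percent; for each length the left bar is library 1 and the right bar library 2. The 5′ U share peaks at 21 nt, at 72.5% of reads but 41.1% of distinct sequences, and the 5′ A share of reads is highest at 24 nt, at 45.6%.

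Beyond the 5′ base, the ends of distinct 24-nt sequences differed from their inner positions. A at the first base was 13.0 ± 0.235 points above its inner share of 31% (SD, n = 2), and U at the last base was 4.19 ± 0.891 points above its inner share of 29.8% (SD, n = 2). The bases at inner end positions given next were picked after their values were seen. G at the next-to-last base was 10.4 ± 0.586 points above its inner share of 20.2%, and U at the next base inward stood at 19.3% ± 0.277 against an inner share of 29.8% (SD, n = 2). In 21-nt sequences, U at the first base was 11.7 ± 0.348 points above its inner share, and A at the next-to-last base stood at 21.6% ± 0.103 against an inner share of 29.6% (SD, n = 2). With 1 adapter type in the series, no comparison of adapters can be made from these shares.

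Reads that matched the fixed lists of miRNA families and of the trans-acting siRNA tasiARF made up 105505 ± 2451 RPM, or 10.6% ± 0.245 of all reads (SD, n = 2). They formed 39.4% ± 0.00882 of the 21-nt reads and 16.2% ± 1.64 of the 22-nt reads, but only 0.0303% ± 0.00107 of the 24-nt reads (SD, n = 2). Of the 40 listed families, 35 had a read in at least 1 library and 30 reached 10 RPM in both. The 4 most abundant families, miR396, miR159, miR167 and miR166, carried 82.7% ± 0.114 of the listed reads (SD, n = 2) in the main match; with up to 2 mismatches miR156, at 13801 RPM, took the place of miR166, at 8853 RPM. The listed sequences of miR828, miR827, miR482, miR2109 and miR2119 had no matching read. This does not bound the level of a family whose sequence in the plant differs from the listed one. With up to 2 mismatches miR2109 had 0.434 RPM in library 1 and 0.176 RPM in library 2, miR482 had 0.261 RPM in library 1 and none in library 2, and the other 3 had none. These 5 were named after their values were seen.

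The list of conserved regulators of transcription factors and auxin signalling held 88.9% ± 0.117 of the listed reads (SD, n = 2), and 14 of its 15 families reached 10 RPM in both libraries. miR396, which targets GROWTH-REGULATING FACTOR genes, was the most abundant family at 37677 ± 6905 RPM. It was followed by miR159, which targets MYB genes, at 20588 ± 9174 RPM, by miR167, which targets AUXIN RESPONSE FACTOR genes, at 17867 ± 2043 RPM, and by miR166, which targets class III HD-ZIP genes, at 11112 ± 2133 RPM (SD, n = 2 for each). The order of miR159 and miR167 holds for the mean and in library 2, with 27075 and 16423 RPM, but not in library 1, with 14101 and 19312 RPM. The SPL regulator miR156 stood at 2159 ± 172 RPM, the NAC regulator miR164 at 1089.7 ± 262 RPM, the TCP regulator miR319 at 1019 ± 100.1 RPM and the AP2 regulator miR172 at 794 ± 29.3 RPM (SD, n = 2 for each). miR160 was at 499 ± 6.77 RPM, miR171 at 328 ± 42.9 RPM, miR169 at 217 ± 84.5 RPM, miR393 at 185 ± 20.5 RPM and miR394 at 156 ± 25.1 RPM (SD, n = 2 for each). tasiARF, which also targets AUXIN RESPONSE FACTOR genes, was at 155 ± 7.69 RPM (SD, n = 2).

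The value of miR156 depended strongly on the match rule. A read of 21 nt, TTGACAGAAGATAGAGGGCAC, was the fourth most abundant sequence by mean, at 11435 ± 3423 RPM (SD, n = 2). In library 1 it had 13855 RPM and stood above the leading miR159 sequence, at 12624 RPM. This 21-nt read differs from a listed miR156 sequence by A17G, counted from the 5′ end of the listed sequence. That position falls inside the stretch that had to match. With up to 2 mismatches allowed, miR156 rose to 13801 RPM. The 4 other most abundant sequences were TTTGGATTGAAGGGAGCTCTA of miR159 at 18423 ± 8201 RPM, TTCCACAGCTTTCTTGAACTT and TTCCACAGCTTTCTTGAACTG of miR396 at 17076 ± 2554 and 16415 ± 3774 RPM, and TGAAGCTGCCAGCATGATCTG of miR167 at 9937 ± 3256 RPM (SD, n = 2 for each).

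Of the 6 families that trigger secondary siRNA from NBS-LRR disease resistance genes, 3 reached 10 RPM in both libraries. miR1507 stood at 2264 ± 402 RPM and miR2118 at 1928 ± 112 RPM (SD, n = 2). Both were led by 22-nt RNA, the length known to trigger secondary siRNA, which made up 89.1% ± 1.1 of miR1507 reads and 89.7% ± 0.827 of miR2118 reads (SD, n = 2). The total of this list also depended on the match rule, at 4232 ± 292 RPM in the main match and 9745 ± 186 RPM with up to 2 mismatches (SD, n = 2). The most abundant reads gained were TTTCCAATTCCACCCATTCCTA, which differs from the listed miR2118 sequence by A3T and G6A and had 4412 ± 297 RPM, and TACGTGTGTCTTCACCTCTGAA, which differs from the listed miR5213 sequence by G5T and had 1285 ± 363 RPM (SD, n = 2). miR5213 is named here after its values were seen.

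Of the 3 families that target the small RNA machinery itself, miR168, which targets AGO1, was at 1547 ± 108 RPM, and miR162, which targets DCL1, at 1508 ± 322 RPM (SD, n = 2). Of the 7 nutrient families, 4 reached 10 RPM in both libraries. miR398, which targets copper/zinc superoxide dismutase genes, was at 1675 ± 626 RPM, miR408, which targets genes of copper proteins, at 249 ± 77.1 RPM, and miR2111, which responds to phosphate, at 166 ± 29.3 RPM (SD, n = 2 for each). Of the 8 other legume families, 6 reached 10 RPM in both libraries, led by miR1511 at 983 ± 596 RPM and miR1509 at 617 ± 352 RPM, with miR2199 at 198 ± 34.9 RPM and miR2643 at 164 ± 31.7 RPM (SD, n = 2 for each). The order of miR1511 and miR1509 holds for the mean and in library 1, but not in library 2, with 562 and 865 RPM.

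The match rule moved the values of many named families by over 1.5 times. Counted only as reads identical to a listed sequence, 13 of the 25 did so. miR167 was then at 128 RPM, as its leading sequence differs from the listed one by A21G, miR1511 at 69.03 RPM and miR1509 at 30.03 RPM. In the same count miR172 was at 412 RPM, miR319 at 269.6 RPM, miR171 at 190.2 RPM, miR2111 at 14.2 RPM, miR393 at 9.13 RPM, miR169 at 3.58 RPM, miR394 at 2.49 RPM and tasiARF at 0.219 RPM, and miR398 and miR408 were at 928 and 139.9 RPM. With up to 2 mismatches, the 5′ end fixed and reads shorter than the listed sequence left out, 6 families moved as much. These were miR156 and miR2118 (both higher), miR394 at 2.58 RPM, miR319 at 649.9 RPM, miR398 at 945 RPM and miR408 at 142 RPM. The gains of miR156 and miR2118 came largely from the reads with substitutions given above. miR394, miR319, miR398 and miR408 had 1.74%, 65.4%, 61.9% and 62.6% of their reads at the listed 5′ end. The median over the 30 families with enough reads was 98.2%. Each change of rule was not tested alone.

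**Figure D3:**
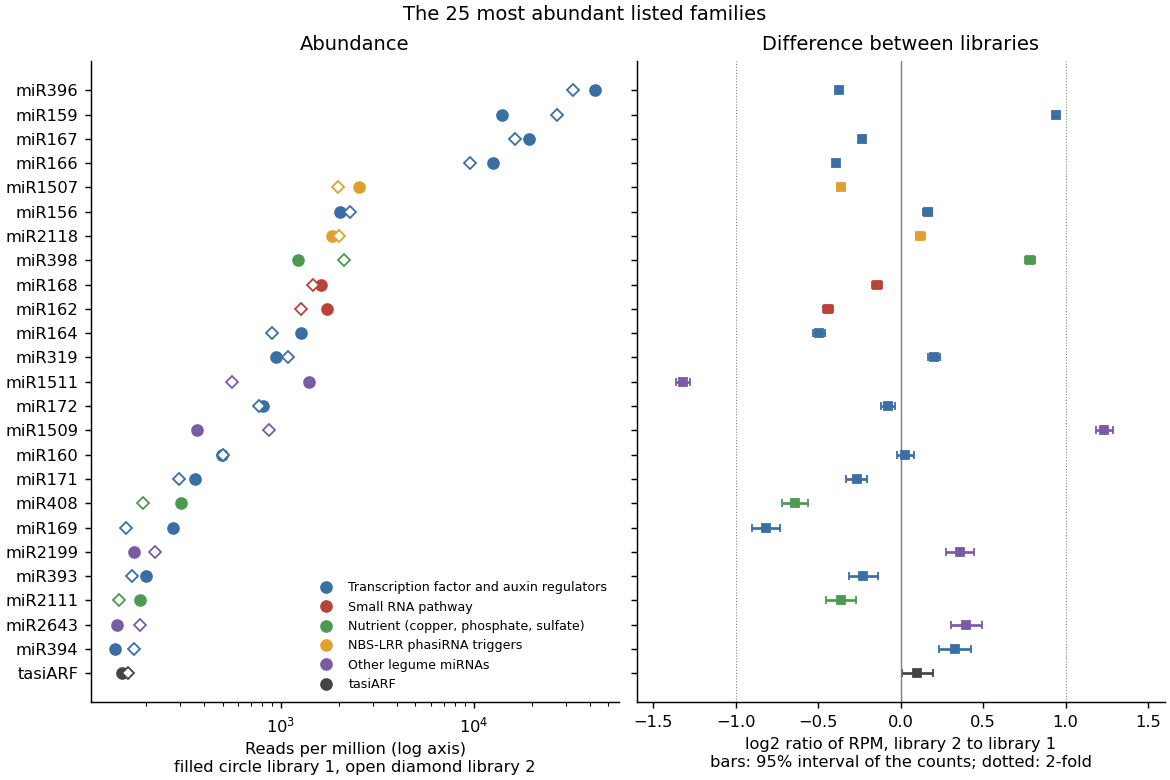
Left, abundance of the 25 listed families with the highest mean, in RPM on a log axis, for library 1 (filled circles) and library 2 (open diamonds), coloured by list; right, log2 ratio of RPM in library 2 to library 1 with the 95% interval of the counts, with dotted lines at 2-fold. By RPM in the main match, only miR1509 and miR1511 lie beyond the 2-fold lines. miR159 lies close to one and passed it when scaled by TMM or DESeq2 factors.

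Most families were led by 1 sequence. Over the 30 families with at least 100 reads in each library, the leading sequence held a median of 81.6% ± 2.46 of the family's reads (SD of the library medians, n = 2), from 25.8% in miR169 to 94.4% in miR160. The leading sequence was 21 nt long in 25 families, 22 nt in 4 and 20 nt in 1, miR156. For miR156 this rests on the match rule, which left out the 21-nt read with A17G. That read had 11435 RPM and the 20-nt leading sequence 1809 RPM. In 21 of the 30 families at least 90% of reads began at the listed 5′ end. miR394 was an exception, with 1.74% ± 0.958 of reads at the listed 5′ end (SD, n = 2), and its leading read was TTTGGCATTCTGTCCACCTCC where the list has TTGGCATTCTGTCCACCTCC. miR395, named here after its values were seen, had 2.15% ± 0.0913 at the listed end (SD, n = 2). In miR398 the share was 61.9% ± 9.98 and in miR319 65.4% ± 0.887 (SD, n = 2). miR167 was mixed in length, with 67.2% of reads at 21 nt and 27.4% at 22 nt in library 1, and 50.7% and 44.6% in library 2.

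The libraries ranked the families alike but differed in single families by more than counting error. Across the 35 families with a read, Pearson's r of log2(RPM + 1) was 0.988 and Spearman's rho 0.967. These are correlations across families, which are not independent replicates. Of the 30 families at 10 RPM or more, 23 lay within 1.5-fold between the libraries. By RPM, 17 had the higher value in library 1 and 13 in library 2, a split that became 15 and 15 when scaled by TMM factors. TMM and DESeq2 factors were computed from the counts of the listed families themselves. This centres their ratios, so a near-even split is partly built in. Among these 30, only miR1509 and miR1511 differed by 2-fold or more by RPM, and miR159 joined them when scaled by TMM or DESeq2 factors. miR1509 was higher in library 2, with 368 and 865 RPM (log2 ratio 1.23, 95% counting interval 1.18 to 1.29), and miR1511 was higher in library 1, with 1405 and 562 RPM (log2 ratio -1.32, interval -1.36 to -1.28). miR159 stood at 14101 and 27075 RPM (log2 ratio 0.94, interval 0.93 to 0.95). miR398 was higher in library 2 (log2 ratio 0.78), while miR169 (-0.82) and miR408 (-0.64) were higher in library 1. All these ratios rest on the main match. Among the named families, miR156 and miR2118 changed direction with up to 2 mismatches. They then had 16128 and 11474 RPM, and 6362 and 6070 RPM, in libraries 1 and 2. By that match miR398 had 801 and 1088 RPM, against 1232 and 2118 RPM in the main match. miR1509 (357 and 840 RPM) and miR1511 (1362 and 540 RPM) stayed at least 2-fold apart.

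In a chi-square test of the read counts of each family against the rest of its library, with Fisher's exact test where a library had under 10 reads, 31 of 35 families passed a Benjamini-Hochberg adjusted p of 0.05. This test compares these libraries, not conditions. The counts of miR160, at 494 and 504 RPM, did not differ beyond counting error by RPM (adjusted p = 0.305 by the chi-square test of read counts). Its log2 ratio was 0.03 by RPM (95% counting interval -0.03 to 0.08), but 0.17 when scaled by TMM factors and 0.13 by DESeq2 factors, both outside that interval. The chi-square of the table of families by library was 2390 times its degrees of freedom, so the counts did not agree within sampling noise and the libraries were kept as 2 samples. At such depth amplified libraries can exceed counting noise whatever their source, so this does not show that they came from separate plants.

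Across single sequences the libraries were less alike. Over all 9156107 sequences Pearson's r was 0.519 and Spearman's rho -0.533; a sequence found in only 1 library is low in the other by construction, which makes the rank correlation negative. Over the 33520 sequences with at least 10 reads in both libraries, r was 0.870 and rho 0.670. These too are correlations across sequences within 1 pair of libraries.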

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

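The tests of long reads in the paragraph on 27 to 32 nt were chosen only after the length distributions had been seen; the correlation with length among abundant sequences had no bound set beforehand, and the other tests on abundant sequences and those on other organisms were set before their results were seen. The lists of miRNAs of other organisms served as a check outside the main measurement and were above the limit that a count of 0 allows (3 reads) in both libraries. Reads identical to listed miRNAs of Arabidopsis or tomato made up 0.608 RPM in library 1 (7 reads) and 2.72 RPM in library 2 (31 reads), and only miR161 exceeded 3 reads in a library. Reads identical to listed animal miRNAs made up 3.74 RPM in library 1 (43 reads) and 8.52 RPM in library 2 (97 reads), with 6 of 14 families above 3 reads in a library, led by miR-486 and let-7a. In a Medicago list, miR403 had 2 reads in library 1 and 34 in library 2, named here after its values were seen. By core match, the rule used for the families, the lists of other plants and of animals had means of 3.81 and 13.7 RPM. These levels and that of miR403 are far below those of the 25 named families by the same rule, the lowest of which had 155 RPM. Counted as identical reads, tasiARF, miR394 and miR169 were at 0.219, 2.49 and 3.58 RPM, below the animal list at 6.13 RPM (means). The leading read of each of these families is not a listed sequence, so the identical count leaves out most of their reads. By core match they were at 155, 156 and 217 RPM.

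Reads of 27 to 32 nt took 2.04% of library 1 and 3.39% of library 2, and the ratio of library 2 to library 1 was 1.17 at 27 nt and 2.36 at 32 nt. A difference in how the gel band was cut is a candidate explanation that stays open. Sequences of 28 to 32 nt without the A box motif of tRNA genes from position 8 were compared with 24-nt sequences. Each had at least 50 reads, and sequences with the motif at another position counted as without it. The median log2 ratio of library 2 to library 1 was 0.94 higher in the long class (bootstrap 95% interval 0.82 to 1.096). Any cause that raises long reads would give such a value, so it does not single out the gel. Within these libraries, reads of the same length did not all shift alike. Over 29 to 32 nt, 87 sequences with that motif from position 8, as in 5′ fragments of tRNA, exceeded others of the same length. The further difference was 0.67 on the log2 scale (interval 0.42 to 1.38). This comparison was set after the data had been seen and uses the same reads. It therefore describes the pattern and does not test a cause. Length variants of 1 RNA are not independent, so both bootstrap intervals may be too narrow, and they cover only this pair of libraries. Reads with the motif rose from 1449 to 6090 RPM and held 34.3% of the excess over 27 to 32 nt, between the bounds set for and against them as its main source. Their part grew with length, to 3645 of 7502 RPM of excess at 30 to 32 nt and 1333 of 2095 RPM at 32 nt. With 1 group in the design, no biological explanation was tested.

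Single abundant sequences differed between the libraries. Over the 615 sequences with at least 1000 reads, the mean chi-square per degree of freedom was 503 and the median chi-square 74.6, and 123 of them were at least 2-fold apart. Separate libraries of amplified reads can exceed counting noise at such depth whatever the source, so these values are given as a description only. GC content may contribute, with a Spearman's rho of -0.18 across sequences (permutation p = 0.0001, the smallest 10000 permutations can give), and the first 2 and last 2 bases explained 7.004% of the variance, against at most 2.17% in 100 permutations. Sequence length had a larger rho, 0.22 (permutation p = 0.0001, again the smallest possible). The values for GC content and end bases lie between the bounds set in advance, and many of the sequences are variants of each other, so neither was decided, and length was not weighed against a bound. A difference between the plants or leaves sampled stays open and was not tested.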

How the results depend on the processing

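For results that are means of the libraries, leaving out either one cannot move them by more than the spread between the libraries; the 24-nt share then ranged from 48.5% to 49.7%. For 24-nt, 21-nt and 22-nt shares and the gap of 24 over 21 nt, sequences with at least 2 reads gave 43.6%, 27.9%, 8.49% and 15.7 points, and sequences found in both libraries gave 36.4%, 34.0%, 9.50% and 2.44 points. Distinct sequences gave 66.2%, 6.32%, 5.29% and 59.9 points, and removing the listed miRNA reads gave 55.0%, 14.6%, 7.21% and 40.4 points. Over all reads of the library the 24-nt and 22-nt shares were 47.8% and 7.47%. The gap kept its direction in each of these; the cause of the moves was not tested. For 5′ A at 24 nt and 5′ U at 21 and 22 nt, the values were 47.5%, 75.7% and 65.2% with at least 2 reads, 49.2%, 77.3% and 69.7% in sequences found in both libraries, and 44.0%, 41.1% and 33.3% over distinct sequences. With at least 2 reads, A at the first base of 24-nt sequences was 15.7 points above its inner share, and U at the last base of 21-nt sequences was at -2.46 points where all sequences gave -1.19.

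Listed reads summed to 108445 RPM of the 18 to 26 nt reads, to 72601 RPM for reads identical to a listed sequence, to 112400 RPM with up to 2 mismatches and to 103026 RPM at 20 to 22 nt. The identical match moved 13 of the 25 named families by over 1.5 times. The match with mismatches, which also fixes the 5′ end and drops shorter reads, moved 6. The other denominator and the length limit moved 0. The leading sequence held a median of 92.1% with up to 2 mismatches. Dropping shifted and shorter reads can itself raise this share, so the move cannot be put down to mismatches alone. The correlation across families was 0.982 with a pseudocount of 0.1 and 0.988 with 10, and that across sequences was 0.870 with at least 10 reads in both libraries. Among the 30 families at 10 RPM or more in both libraries, miR1509 and miR1511 were at least 2-fold apart by all 4 scalings. They were joined by miR159 under TMM and DESeq2 factors. These factors shifted all ratios by 0.14 and 0.11 on the log2 scale and changed the sign of 2 and 1 of the 30 families. Core matches gave 3.81 RPM for miRNAs of other plants and 13.7 RPM for those of animals. The genome classes were not run, as no genome sequence was used here. Reads were not subsampled, so how far depth limits the recovery of distinct sequences was not tested; of those of library 1, library 2 held 22.9% at 21 nt, 11.9% at 23 nt, 25.9% at 24 nt and 7.88% at 25 nt.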

Other observations

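The test of antisense partners over both libraries was set before its result was seen; the tests in each library alone and the other items here were chosen after their values were seen. Several of the 20 most abundant sequences of 18 to 26 nt lay outside the listed families. GGAATGTTGTCTGGCTCGAGG, known as the passenger strand of miR166, had 2480 ± 94.6 RPM, while the listed miR166 sequence had 8294 ± 1786 RPM (SD, n = 2). TCGTCATGAAAGTCAAGGGCC had 4353 ± 206 RPM and TTAATCAGGGAAATCACAGTT 2964 ± 1777 RPM (SD, n = 2), and neither came within 2 mismatches of a listed sequence. Within miR167, the 21-nt read TGAAGCTGCCAGCATGATCTG was lower in library 2 (log2 ratio -0.68) and the 22-nt read TGAAGCTGCCAGCATGATCTGG, which adds 1 base at its 3′ end, was higher (0.65).

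A group of reads shared the last 15 bases CCGGTAGACTTGAAC over every length from 18 to 32 nt. It had 12719 ± 1023 RPM (SD, n = 2), more than the miR166 family, and formed no peak at 21 or 24 nt: 780 ± 38.0 RPM at 21 nt, 407 ± 32.03 at 24 nt and 2732 ± 658 at 25 nt (SD, n = 2). Its origin was not assigned here.

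Dicer-like enzymes cut double-stranded RNA to duplexes with a 2-nt 3′ overhang, so 24-nt partners on opposite strands may overlap by 22 nt. Of 5892548 distinct 24-nt sequences, 14.4% had a 24-nt partner at an overlap of 22 nt, which was 1.09 times the mean of 13.1% at 20, 21, 23 and 24 nt. A ratio of at least 1.5 had been set as the sign of such cuts and one of at most 1.1 as evidence against them. The ratio over both libraries, 1.095, lay just under the lower bound, while library 1 alone gave 1.103 and library 2 alone 1.107, just above it. The libraries were examined singly only after the ratio over both had been seen, and because the distance to the bound is smaller than the spread of these values, the test was read as undecided. For 21-nt sequences the ratio at an overlap of 19 nt was 1.081 over both libraries, 1.089 in library 1 and 1.098 in library 2. In each library alone 19 nt had the highest share of the overlaps searched, in library 1 with 9.72% against 9.67% at 17 nt. Over both libraries the highest was 15 nt, with 11.64% against 11.13% at 19 nt. The search asked only for complementary bases over the overlap, so shorter overlaps are met more easily. A maximum at 15 nt is therefore no evidence against a peak at 19 nt, or at 22 nt for 24-nt sequences. For 22-nt sequences the ratio at 20 nt was 1.108, 1.111 and 1.135. For 24-nt sequences over both libraries, partners were common at all overlaps searched, from 11.98% at 23 nt to 20.2% at 15 nt, and without a genome, reads from repeated or inverted sequences cannot be told apart from cut duplexes.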
